A study of Homo sapiens with 4 samples.

How the data were processed

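RNA was measured in 4 libraries of MDA-MB-231, a triple-negative breast cancer cell line. Per the labels, 2 libraries came from cells with a knockdown of AURKA and 2 from control cells, which the series design text describes as mock-transfected and the titles call shC, which leaves open whether they carried a hairpin. The design text calls the 2 libraries of each group biological replicates. The p-values of the main comparison measure the spread between these samples. Those of the fit with the replicate number as a block, described below, measure only how far the 2 differences between knockdown and control disagree. In both fits the spread of a gene is moderated by that of other genes. Nothing in the labels says whether the samples came from separate days, so the spread between them may be smaller than that between independent experiments. Per the labels' protocols, the cells were grown in L-15 medium with serum, total RNA was taken with an RNeasy kit, and libraries were made with the NEBNext Ultra RNA kit.

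The authors deposited 1 table per library with a value for each of 81493 annotated transcripts. The header names no unit. The deposited values were read as FPKM (fragments per kilobase of transcript, scaled by library depth), from the values themselves: they are not whole, their totals differ between libraries, and low values step by whole reads with a step set by the gene. The submitters' processing notes name bcl2fastq 2.19, HTSeq 0.8.0 and the build hg38. HTSeq gives whole counts, and the program that made the deposited FPKM values is not given in the sources used here. The coordinates in the files are those of GRCh37, since a locus on chromosome 4 ends at 191013719, beyond the end of that chromosome in GRCh38. Coordinates are therefore given as in the files, as GRCh37, 1-based, and they are of loci that can join overlapping genes. The kit name does not state a strand setting, so reads of overlapping and antisense genes cannot be told apart.

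Row order was the same in the control and knockdown tables of a replicate number and differed between the numbers. Tables were joined by transcript ID, and 81412 transcripts stood in all 4. A further 81 stood only in the replicate 1 tables and 81 only in the replicate 2 tables, and 1707 shared transcripts carried another locus in replicate 2. Each replicate number was thus quantified in its own run, 1 library of each group per run. Transcript values were summed to 20137 genes by gene ID. Gene symbols are those of the files, except for 29 genes whose symbol had turned into a date, of which 28 were named through their ID. GENCODE 29 gave a biotype for 19333 gene IDs and the transcript sequences, and none of its coordinates were used.

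The files hold no read totals. In genes with 1 transcript and values under 0.3 FPKM, ratios between 2 libraries fell within 0.3% of ratios of whole numbers up to 6 times a constant. This held for 58.5% of 605 genes between the replicate 1 libraries, against 2.0% at the median other constant, and for 50.7% of 590 genes between the replicate 2 libraries, against 2.2%. Across the replicate numbers it held for fewer, 31.0% of 520 genes between the controls and 27.8% of 626 genes between the knockdown libraries. With GENCODE 29 transcript lengths over 2000 bases, the value of 1 read gave estimated depths of 17300000 fragments for control replicate 1, 24400000 for control replicate 2, 21100000 for knockdown replicate 1 and 27800000 for knockdown replicate 2. These rest on the main cluster of estimates, 95 of 183 genes in each replicate 1 library and 92 and 91 of 169 in the replicate 2 libraries, so they are rough. Whole reads could not be recovered for most genes, which have several transcripts, so no count test was run.

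The design fixed before the data were examined named edgeR's quasi-likelihood test for counts and, without counts, limma-trend on log2(value + 1). The second was used (limma 3.58.1, R 4.3.3), on log2(FPKM + 1), for 12136 genes with at least 1 FPKM in at least 2 libraries. That filter was set after the unit was known and before any test. Fold changes on this scale understate the change of low genes. The test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The main comparison has no replicate block, as fixed. The labels do not say what a replicate number marks, and with 2 pairs the numbers alone would not pair the libraries. The files show, however, that the number is also the quantification run. The value from the alternative, chosen beforehand, with the replicate number as a block is therefore printed beside results as "with the run as a term". The number may mark separate cultures as well. The term removes both kinds of difference, and they cannot be told apart here.

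On simulated data with the real genes' levels and run differences (12136 genes, 200 of them changed, 20 simulations), the fit without the run recovered 0% of 1.5-fold, 1% of 2-fold and 55.2% of 4-fold changes, and 0.1% of its calls were false. With the run as a term it recovered 41.2%, 78.7% and 95.7%, and 12.4% of its calls were false, above the nominal level. Lists were tested with camera in limma (preset correlation 0.01). A list of mitosis genes lowered by 0.3 on the log2 scale was called in 20 of 20 simulations, and 2 of 420 tests of unshifted lists were called. Apart from the run differences, noise was drawn for each gene on its own. These rates therefore do not cover lists whose members vary together.

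There were 23 gene lists, fixed before the data were examined. The text names genes by a rule fixed at the same time: 7 genes linked to AURKA in breast cancer stem-like cells (AURKA, DROSHA, STC1, MYC, FOXM1, METTL14 and IGF2BP2), the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean log2 value of at least 1 and groups that do not overlap, the 5 smallest p, and members of each list with the smallest p. Since no gene passed without the run, the parts of the rule that need a passing gene were applied to the fit with the run as a term, a step chosen after the data were seen. The rule gave 72 different genes. Other genes in the text, among them further members of the lists, were chosen after their values were seen.

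Alternatives were other scalings of the FPKM values (median of ratios, equal totals, upper quartile), no filter or a filter at 5 FPKM, leaving out each library, the replicate block, robust empirical Bayes, protein-coding genes only, stricter thresholds, and, for lists, an estimated correlation, ranks and fry. Pseudocounts of 0.1 and 5, quantile normalization, leaving out genes with the 7-base word described in the closing section, and combinations with the block were added after seeing the data. TMM factors, DESeq2, limma-voom and the robust quasi-likelihood fit need counts and were not run. With an estimated correlation camera also tests on the few residual degrees of freedom that 4 libraries leave. A call can thus be lost there without correlation among the members of a list. Annotated 3′ UTRs of at least 50 bases (the longest per gene, GENCODE 29) were searched in 11661 tested genes. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.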

Results

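Gene expression was measured by RNA sequencing in MDA-MB-231 cells, a line from a triple-negative breast cancer, with a knockdown of AURKA (2 libraries) and in control cells (2 libraries). AURKA encodes Aurora kinase A, a mitotic kinase. The series title frames the question as which genes AURKA regulates at the level of transcription. The summed FPKM values were 720602 and 761641 in control replicates 1 and 2 and 747994 and 718978 in knockdown replicates 1 and 2. Estimated depths were 17300000, 24400000, 21100000 and 27800000 fragments in the same order. Between 11738 and 12177 genes reached 1 FPKM, and mitochondrial transcripts took the most in knockdown replicate 1, at 19.0% of the total.

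AURKA was 4.86-fold lower in the knockdown. Its values were 124 and 99.1 FPKM in the controls and 22.3 and 23.7 FPKM in the knockdown (111.6 ± 17.7 and 23.0 ± 0.96, SD, n = 2 each), a log2 difference of -2.22 with a standard error of 0.15. The gene (ENSG00000087586) lies on chromosome 20 at 54944445 to 54967393 (GRCh37). The fall in each run was -2.42 and -2.02 on the log2 scale. The adjusted p was 0.0819 in limma without the run and 0.000696 with the run as a term. Both knockdown libraries lay below both controls, as the labels would have it.

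Among the genes linked to AURKA beforehand, DROSHA and STC1 were lower in both knockdown libraries and MYC, FOXM1 and METTL14 differed by less than 1.2-fold. DROSHA, the nuclease that starts microRNA processing (ENSG00000113360, chromosome 5, 31400604 to 31532303), had 42.2 and 44.1 FPKM in the controls and 24.4 and 27.6 FPKM in the knockdown (log2 -0.71, standard error 0.13, adjusted p 0.402 without and 0.0132 with the run as a term). STC1, a secreted glycoprotein hormone (ENSG00000159167, chromosome 8, 23699428 to 23712320), had 50.2 and 19.5 FPKM in the controls and 10.9 and 10.7 FPKM in the knockdown (log2 -1.46, standard error 0.42, adjusted p 0.582 and 0.0379). Its size rests on control replicate 1: the log2 difference was -2.10 in the first run and -0.81 in the second. IGF2BP2, an RNA-binding reader of m6A, had 48.2 and 48.2 FPKM against 37.1 and 37.1 FPKM, with an adjusted p of 0.628 and 0.0614. MYC was at 19.1 ± 1.3 and 20.5 ± 1.5 FPKM, FOXM1 at 54.7 ± 12.7 and 57.8 ± 9.97 FPKM, and METTL14 at 10.7 ± 0.86 and 12.1 ± 0.91 FPKM in control and knockdown (SD, n = 2 each), and none of the 3 passed in either fit. The annotated 3′ UTRs of DROSHA and METTL14 hold the 7-base word GAGACCT, which the closing section takes up, and that of STC1 does not.

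**Figure D1:**
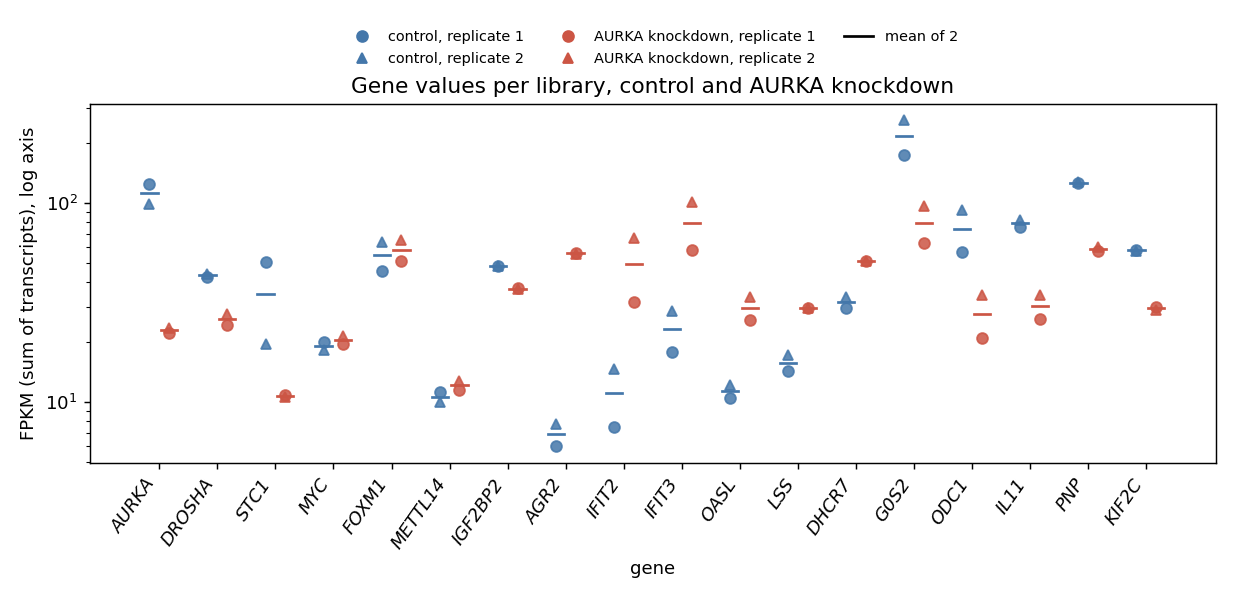
FPKM (log axis) of 18 named genes in each library, with control in blue, knockdown in red, circles for replicate 1, triangles for replicate 2 and lines for the mean of 2. AURKA lies at 99.1 to 124 FPKM in the controls and at 22.3 to 23.7 FPKM in the knockdown, and AGR2 at a mean of 6.89 and 55.7 FPKM.

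Across the transcriptome, AGR2 was the gene with the smallest p. This protein disulfide isomerase of secretory epithelia (adjusted p 0.0581 in limma without the run, 0.000573 with it) had 6.89 ± 1.25 FPKM in the controls and 55.7 ± 0.22 FPKM in the knockdown (SD, n = 2 each), 8.09-fold higher. Higher as well were the mucins MUC5AC (5.67 and 2.22 to 29.9 and 11.6 FPKM) and MUC5B (2.37 and 1.28 to 15.3 and 6.58 FPKM), and S100P, a calcium-binding protein (2.12 ± 0.66 to 11.6 ± 0.66 FPKM, SD, n = 2 each). The monocarboxylate transporter SLC16A12 (0.937 and 1.075 to 5.49 and 3.53 FPKM) and the focal adhesion gene TNS4 (6.02 and 3.42 to 20.5 and 8.52 FPKM) were 4.48-fold and 3.08-fold higher. These genes passed with the run as a term (adjusted p 0.00117, 0.00405, 0.00245, 0.0176 and 0.0105) and not without it. Of the 10 largest rises, IFIT2, IFIT3 and OASL belong to the interferon list described further on, and CTD-2370N5.3 shares its locus with another gene and is uncertain.

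Among the 10 largest falls, led by ECSCR and then AURKA, was G0S2, an inhibitor of lipolysis, at 174 and 260 FPKM in the controls and 62.7 and 96.2 FPKM in the knockdown (log2 -1.44 ± 0.28, standard error), and so was ODC1, the rate-limiting enzyme of polyamine synthesis, at 56.6 and 91.8 FPKM against 21.0 and 34.5 FPKM (log2 -1.39 ± 0.32). IL11, a cytokine, fell from 78.7 ± 4.6 to 30.2 ± 5.7 FPKM (SD, n = 2 each) with the run as a term (adjusted p 0.00245). BCL2A1, an anti-apoptotic BCL2 family member (11.9 and 5.40 to 3.06 and 1.015 FPKM), CCM2 (18.0 and 18.2 to 6.74 and 3.97 FPKM) and the integrin ITGA2B (3.36 and 2.49 to 0.45 and 0.13 FPKM) were 4.25-fold, 3.38-fold and 9.95-fold lower. The ITGA2B values in the knockdown lay below 1 FPKM, so its fold is uncertain. KRTAP2-3 was 3.21-fold lower, and since keratin-associated proteins have near-identical copies, its value is uncertain. PNP, a purine salvage enzyme, had 125 and 127 FPKM in the controls and 57.0 and 59.7 FPKM in the knockdown (log2 -1.10 ± 0.11). Each of these genes passed with the run as a term (adjusted p 0.000824 to 0.00902) and not without it (0.227 to 0.569). ECSCR (chromosome 5, 138784245 to 138784863) was listed at 0 in both knockdown libraries and at 11.3 and 4.18 FPKM in the controls (adjusted p 0.00719 with the run). Its fold has no finite value and the controls differ, so the size of its fall is uncertain. AL160274.1, which shares its locus on chromosome 9 (35161999 to 35405335) with another gene, was listed at 0 in both controls and at 15.8 and 9.32 FPKM in the knockdown. The 3′ UTRs of CCM2, IL11, PNP and TNS4 hold the word GAGACCT.

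In all, limma without the run called 0 of 12136 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0581 and 773 genes at an unadjusted p under 0.05 (370 higher and 403 lower in the knockdown). With the run as a term it called 417 genes, 186 higher and 231 lower, of which 56 changed at least 2-fold (26 higher and 30 lower). The 2 groups did not overlap in 35.9% of all tested genes, against 33.3% by chance, so a lack of overlap alone says little about a gene. In all tested genes, 66.8% had the same sign in both runs, against 50% by chance. Across genes, which are not independent replicates, the difference in run 1 correlated with that in run 2 at r = 0.481. Leaving out 1 library gave 6 (control replicate 1), 15 (control replicate 2), 7 (knockdown replicate 1) and 10 genes (knockdown replicate 2), without the run. With the run as a term, 887 genes passed with median-of-ratios scaling, 890 with upper-quartile scaling, 131 without the genes holding GAGACCT and 0 with no filter on low values. Of the searched genes among the 417, 93 called lower and 15 called higher hold that word. The fall to 131 is larger than that, so genes without the word lost their call as well.

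**Figure D2:**
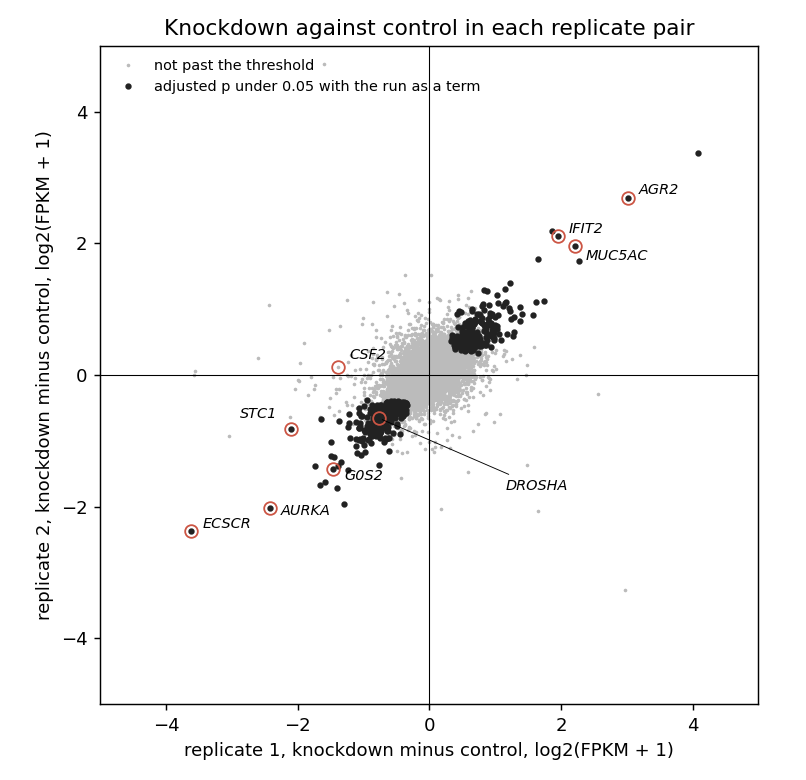
Difference between knockdown and control on the log2(FPKM + 1) scale, with replicate 1 on the x axis and replicate 2 on the y axis, 1 point per gene. The 417 genes past the threshold with the run as a term (black) lie in the quadrants where both runs have the same sign, with AURKA at -2.42 and -2.02 and AGR2 at 3.02 and 2.69.

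Genes of cholesterol synthesis were higher in the knockdown as a group. Of 19 tested members, 18 had a higher mean, and 6 rose and 0 fell with the run as a term: LSS (14.3 and 17.2 to 29.6 and 29.7 FPKM), DHCR7 (29.8 and 33.7 to 51.0 and 51.3 FPKM), HMGCS1, MVK, CYP51A1 and SREBF2, the transcription factor of this pathway, whose 3′ UTR holds the word GAGACCT. The list's median was 0.36 on the log2 scale, 0.30 in run 1 and 0.43 in run 2 (camera adjusted p 7.97e-09 without and 2.31e-09 with the run). The call is lost with an estimated correlation (adjusted p 0.479, and 0.751 with the run). The correlation estimated without the run was -0.04, below the preset of 0.01. Correlation among members therefore does not account for the loss without the run. Without the run 0 members passed over all genes. Adjusted over the list alone, 4 were higher and 0 lower without the run, and 15 higher and 0 lower with it.

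Genes of the type I interferon response were higher too, with 24 of 26 tested members above 0. With the run as a term 7 rose, among them IFIT2 (7.47 and 14.7 to 31.8 and 66.7 FPKM), IFIT3 (17.8 and 28.7 to 58.0 and 100.4 FPKM), IFIT1 (26.6 and 33.1 to 60.1 and 83.1 FPKM) and OASL (10.5 and 12.1 to 25.9 and 33.7 FPKM), with ISG15, IFI27 and DDX58. The 3 IFIT genes share 1 locus in the files and are not independent of each other. IFITM2 fell with groups that overlap (110.3 and 73.2 to 76.7 and 48.2 FPKM, adjusted p 0.0195 with and 0.822 without the run), with a close paralog, IFITM3, at 247 and 197 against 253 and 194 FPKM. The list's median was 0.30, 0.25 in run 1 and 0.33 in run 2 (camera adjusted p 1.28e-07 without and 3.85e-08 with the run). This call too is lost with an estimated correlation (adjusted p 0.689, at an estimate of 0.08). Without the run 0 members passed over all genes. In the same terms as above, adjusted over the list alone, 5 were higher and 0 lower without the run, and 12 higher and 1 lower with it.

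Mitosis and G2/M genes were slightly lower as a group (34 tested, median -0.10, camera adjusted p 0.00157, and 0.00333 with the run), a call lost with an estimated correlation (adjusted p 0.74). KIF2C, a microtubule depolymerase (57.8 ± 0.27 to 29.6 ± 0.81 FPKM, SD, n = 2 each), and AURKB, the kinase of the chromosomal passenger complex (70.7 and 54.2 to 45.1 and 36.3 FPKM), fell with the run as a term, and the other 32 members did not pass. The 3′ UTRs of both hold the word GAGACCT. CCNB1, CDC20, BUB1 and TOP2A each differed by less than 0.1 on the log2 scale. The median was -0.21 in run 1 and -0.004 in run 2, and the adjusted p was 0.346 without knockdown replicate 1. Adjusted over the list alone, 0 were higher and 1 lower without the run, and 0 and 2 with it. In the list of AURKA and its regulators and partners, 18 were tested, AURKA and AURKB fell and AJUBA rose with the run as a term, and TPX2, the activator of AURKA, was at 168 and 173 against 158 and 172 FPKM (camera adjusted p 0.202).

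NF-kappaB targets and cytokines differed between the runs. Their median was -1.02 in run 1 and 0.13 in run 2, with 20 of 23 tested members below 0 on average (camera adjusted p 0.0189, and 0.00268 with the run). The call is lost with an estimated correlation (adjusted p 0.788) and with a filter at 5 FPKM (0.0517). Control replicate 1 stood apart in these genes: IL8 (CXCL8) was at 265 and 28.2 FPKM in the controls and 42.7 and 33.9 FPKM in the knockdown, and TNFAIP3 at 23.4 and 2.62 against 7.48 and 4.82 FPKM. Without control replicate 1 the list was higher in the knockdown (adjusted p 0.0053). IL11 and IER3 fell with the run as a term, IER3 with groups that overlap (336 and 117 to 168 and 84.5 FPKM) and, for gene IER3, a log2 difference of 0.023 without control replicate 1. CCL2 was at 14.1 and 7.76 against 19.4 and 19.3 FPKM. Adjusted over the list alone, 0 were higher and 1 lower without the run, and 1 higher and 2 lower with it.

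Endoplasmic reticulum chaperones (19 tested, median 0.14, camera adjusted p 0.0119, and 0.00665 with the run) and ATF4 targets (23 tested, median 0.24, adjusted p 0.0189, and 0.0203 with the run) were higher. Both calls are lost with an estimated correlation (adjusted p 0.74 and 0.689), and that of the ATF4 list also with a filter at 5 FPKM (0.13) and, with the run, without genes holding GAGACCT (0.0565). The correlation estimated without the run was 0.127 for the chaperones and -0.037, below the preset, for the ATF4 list. HERPUD1, a factor of protein degradation at the endoplasmic reticulum, rose with the run as a term (23.0 and 21.5 to 31.1 and 32.9 FPKM), as did NUPR1 (0.162 and 0.172 to 1.06 and 1.87 FPKM, with GAGACCT in its 3′ UTR), and 0 members of either list fell. DNAJB9 (5.59 ± 0.83 against 9.03 ± 0.39 FPKM, SD, n = 2 each) and PSPH (14.4 and 25.9 against 33.8 and 30.3 FPKM) did not pass. The chaperone list did not pass without control replicate 1 (0.253) or knockdown replicate 2 (0.37), and the ATF4 list did not without the same libraries (0.147 and 0.088). Adjusted over the list alone, 0 members of either passed without the run, and 7 chaperones and 1 ATF4 target were higher with it.

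With the run as a term 3 further lists were lower, and with an estimated correlation and the run each had an adjusted p of 0.751. Without the run as a term, MYC targets and heat shock genes turned higher when control replicate 2 (adjusted p 0.484 and 0.453) or knockdown replicate 1 (0.739 for each) was left out, and immediate early genes were at 0.429 without control replicate 1. With the run as a term, of 15 tested immediate early genes, FOSL1 (207 and 216 to 127 and 130 FPKM), EGR1, FOS and IER3 fell and KLF2 rose (27.1 and 22.3 to 67.2 and 35.6 FPKM). The groups overlapped for EGR1 (36.4 and 19.6 to 21.5 and 11.1 FPKM) and IER3, with adjusted p of 0.823 and 0.884 in limma without the run. The list median was -0.70, -0.70 in run 1 and -0.15 in run 2 (camera adjusted p 0.0667 without and 0.00421 with the run). DUSP1 and JUNB were highest in control replicate 1 (113 and 29.9 against 27.6 and 28.4 FPKM for DUSP1). Of 23 MYC targets in ribosome biogenesis, ODC1 and SRM, both enzymes of polyamine synthesis, fell, while NCL, NOP58 and FBL (201 and 232 against 161 and 178 FPKM) did not pass (list median -0.12, adjusted p 0.0574 and 0.0203). Of 13 heat shock genes HSP90AA1 fell (1109 and 1368 to 743 and 954 FPKM) and HSPA4L, with GAGACCT in its 3′ UTR, was at 14.9 and 16.6 against 11.8 and 13.2 FPKM (list median -0.15, adjusted p 0.0707 and 0.0111). With the run and adjusted over the list alone, 9 immediate early genes, 4 MYC targets and 5 heat shock genes were lower and 3, 0 and 1 higher. Without the run the numbers were 1, 0 and 0 lower and 0 higher.

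Other lists did not pass in either fit, with single members that did. Mesenchymal genes went both ways with the run as a term: FN1 (39.5 and 29.9 to 61.7 and 51.6 FPKM) and COL6A1 rose, and TGFBI was among those that fell (17 tested, adjusted p 0.865). Of 22 YAP/TAZ targets ANKRD1 rose (52.1 and 79.1 to 95.9 and 119 FPKM) and F3, ASAP1 and AXL fell (adjusted p 0.342), and the 3′ UTRs of TGFBI and ASAP1 hold the word GAGACCT. E2F1 fell (18.7 and 21.7 to 10.7 and 10.7 FPKM) among 25 genes of G1/S and DNA replication, and RFC4 was at 48.5 and 50.2 against 39.5 and 44.0 FPKM (adjusted p 0.583). Of 21 p53 targets TP53I3 rose (10.5 and 19.1 to 26.7 and 29.3 FPKM), and CDKN1A was 1.55-fold lower without passing (adjusted p 0.865). DROSHA was the 1 passing member of 12 microRNA biogenesis genes, and 10 of the 12, such as AGO1 (11.1 ± 0.90 and 14.2 ± 0.29 FPKM, SD, n = 2 each), had a log2 difference above 0 (adjusted p 0.394). Among 12 breast cancer stem-like cell factors STC1 passed and ITGA6 was at 103 and 107 against 120 and 108 FPKM (adjusted p 0.906), and of 19 genes of m6A methylation 0 passed, with IGF2BP3 at 27.5 ± 3.6 against 33.9 ± 1.1 FPKM (SD, n = 2 each) (adjusted p 0.696).

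Hypoxia and glycolysis genes (22 tested, adjusted p 0.432, with HK2 at 32.8 and 28.6 against 23.8 and 26.8 FPKM and PFKFB3, which holds GAGACCT, 1.27-fold lower), mitochondrially encoded mRNAs (13 tested, adjusted p 0.726, with MT-ATP6 at 6223 and 7865 against 9317 and 8194 FPKM and MT-CYB 1.19-fold higher) and epithelial genes (11 tested, adjusted p 0.109, with TJP1 at 45.2 and 40.6 against 49.7 and 48.9 FPKM and OCLN 1.18-fold higher) had 0 members past the threshold in either fit. Of 10 tested luminal breast markers AGR2 passed with the run as a term, while ERBB3 was at 2.52 and 2.23 against 1.30 and 1.04 FPKM (adjusted p 0.1). Fibroblast markers (3 of 10 tested, with ACTA2 at 2.73 and 2.22 against 1.47 and 1.44 FPKM and COL1A1, which holds GAGACCT, at 3.61 and 1.04 against 2.29 and 1.17 FPKM, adjusted p 0.238) and leukocyte markers (2 of 14 tested, CD68 and LCP1, adjusted p 0.432) had 0 passing members, and the remaining markers of both types lay below the filter. Among the lists of this and the preceding paragraph and AURKA's partners, adjusted over the list alone without the run, 1 gene was lower in each of AURKA's partners, G1/S, microRNA biogenesis and YAP/TAZ and 1 higher among luminal markers. Adjusted over the list alone with the run, higher and lower were 1 and 2 of AURKA's partners, 3 and 4 mesenchymal genes, 3 and 6 YAP/TAZ targets, 2 and 1 luminal markers, 1 and 0 p53 targets, and 0 and 1 in each of G1/S, microRNA biogenesis, stem-like cell factors and leukocyte markers. The other lists had 0. For 3 lists the median and the test or the mean differed in sign: p53 targets had a median of 0.013 and a mean of -0.004, m6A genes 0.007 and -0.013, and stem-like cell factors 0.071 and -0.071, with camera giving lower, lower and higher.

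**Figure D3:**
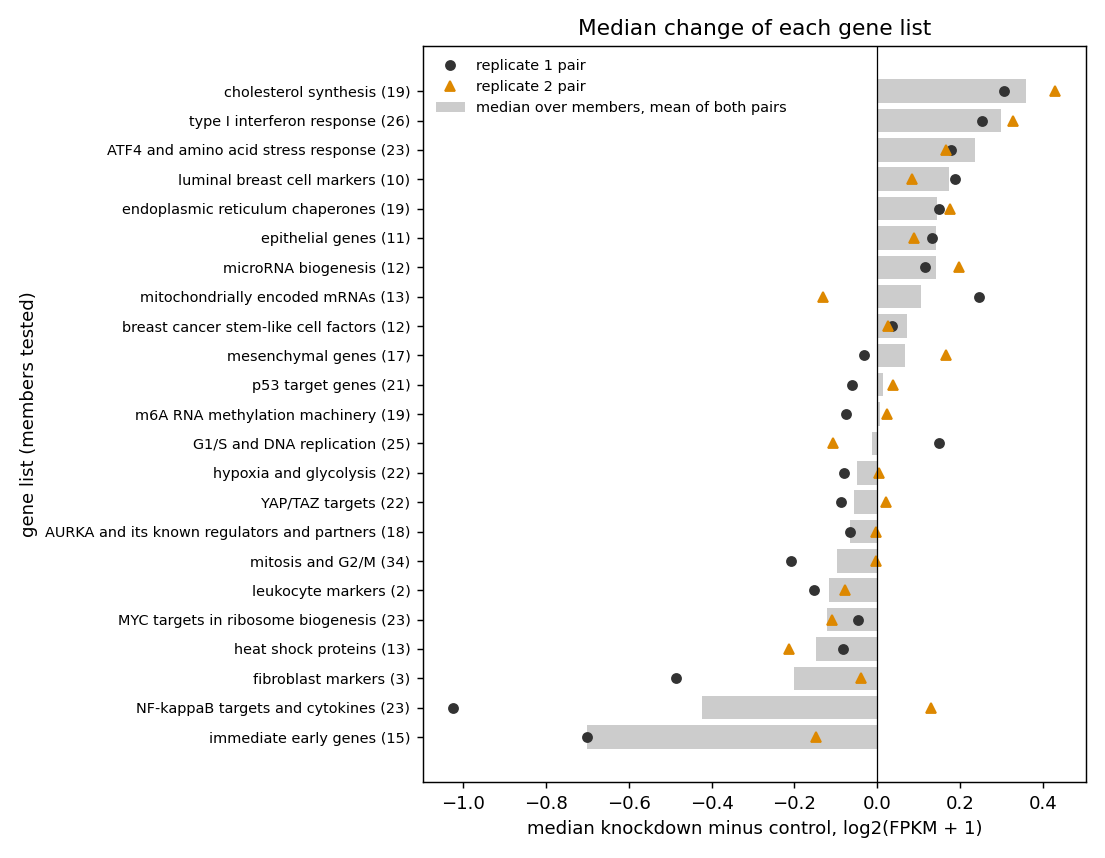
Median difference between knockdown and control on the log2(FPKM + 1) scale for each of 23 gene lists, with the number of tested members in brackets. Bars show the median over members of the mean of both runs, circles run 1 and triangles run 2. Cholesterol synthesis lies at 0.30 and 0.43 and the NF-kappaB list at -1.02 and 0.13.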

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

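Pseudocounts, quantile normalization, leaving out genes with the 7-base word and combinations with the block were chosen after seeing the data, and the other alternatives before. TMM, DESeq2, limma-voom and the robust quasi-likelihood fit need counts and were not run. The cause of the moves below was not tested, except that a lone library is assumed to vary like the other group and that fewer genes are tested with a filter or a left-out class.

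Without the block, limma called 3 genes with median-of-ratios scaling, 2 with equal totals, 2 with upper quartiles, 1 with a filter at 5 FPKM, 1 with a pseudocount of 5, 6 to 15 without 1 library, and 0 otherwise. Deviations of libraries with the same replicate number correlated across genes at r = 0.645, with 2 pairs. The replicate block called 417 genes. Combined with it were 887 (median of ratios), 432 (equal totals), 890 (upper quartile), 0 (no filter, with 2790 at an unadjusted p under 0.05), 424 (5 FPKM), 287 (pseudocount 0.1), 276 (pseudocount 5), 542 (robust), 502 (protein-coding), 131 (word genes left out), 53 (adjusted p under 0.01) and 56 genes (at least 2-fold). Of the 887 and 890 genes, 414 and 415 were among the 417. No scaling moved the median of all genes by over 0.1. A split of replicate 1 against replicate 2 had 2348 genes at an unadjusted p under 0.05 against 773, and the remaining split 27, with 1 called.

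The AURKA level in the knockdown kept its direction throughout. It passed with median-of-ratios scaling (log2 -2.24) and upper quartiles (-2.23), without any 1 library (-2.38 to -2.06), and with the block (-2.22, -2.27 with a pseudocount of 0.1, -2.05 with 5, and -2.24 to -2.22 with the other block combinations except no filter). Of 1800 values of other named genes under alternatives, 1327 kept direction and side of the threshold, 468 passed it and 5 reversed: gene FOXM1 ranged from -0.15 to 0.32, gene IER3 from -1.49 to 0.023 and gene COL1A1 from -0.79 to 0.39 without 1 library.

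The number of lists called was 6. It was 10 with equal totals, 7 to 11 without 1 library and 0 with an estimated correlation. With fry, which tests a list against no change and not against other genes, it was 0. Cholesterol synthesis and interferon were called under all alternatives but those last 2 (adjusted p 0.479 and 0.689 estimated, 0.213 and 0.472 with fry). For the other called lists the estimated correlation and fry gave 0.74 and 0.472 (mitosis), 0.788 and 0.867 (NF-kappaB), 0.689 and 0.213 (ATF4) and 0.74 and 0.472 (chaperones). With a filter at 5 FPKM NF-kappaB was at 0.0517 and ATF4 at 0.13. Newly called were MYC targets (0.0346 with equal totals, 0.0428 with no filter, 0.0203 with the replicate block, 0.0313 without word genes), immediate early genes (0.0346, not without a filter, 0.00421 with the block, 0.0475 without word genes), heat shock genes (0.0444 with equal totals, 0.0111 with the block), luminal markers (0.0346 with equal totals, 0.0325 at 5 FPKM) and, without word genes, microRNA biogenesis (0.0446). The block changed no other list call. Directions of uncalled lists reversed for p53 targets with fry (0.962) and for stem-like cell factors with no filter (0.985) and without word genes (0.953).

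Without 1 library, adjusted p ranged from 9.2e-06 to 0.346 for mitosis, 1.29e-18 to 0.0111 for NF-kappaB (reversed without control replicate 1), 0.00806 to 0.147 for ATF4, 0.000501 to 0.37 for chaperones, 0.0313 to 0.257 for AURKA and partners, 0.0341 to 0.739 for epithelial genes, 0.000407 to 0.429 for immediate early genes and 0.00298 to 0.186 for luminal markers. Direction also reversed in part for G1/S genes (7.65e-07 to 0.0311, lower without control replicate 1 or knockdown replicate 2 and higher without either other library), MYC targets (4.59e-07 to 0.739), heat shock genes (2.84e-06 to 0.739), p53 targets (0.729 to 0.956), stem-like cell factors (0.654 to 0.962), m6A genes (0.33 to 0.962), microRNA biogenesis (0.222 to 0.963), mesenchymal genes (0.129 to 0.739), hypoxia (0.115 to 0.929) and mitochondrial mRNAs (0.0774 to 0.815). Depth was 17300000 to 27800000 fragments by estimate. How far depth limits what could be called was not tested.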

Other observations

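Of the tests in this part, those of word order, of site classes and of the interferon list were chosen after the result was seen, as was the word search itself, and those of places per 3′ UTR, of libraries within a group and of microRNA words before. The genes of this paragraph are in none of the fixed lists and were chosen after their values were seen. SCD, a fatty acid desaturase, was at 102 and 118 FPKM in the controls and 185 and 193 FPKM in the knockdown, although the SCD 3′ UTR holds the word GAGACCT, and FADS2 at 85.9 and 89.4 against 157 and 147 FPKM. FADS1, which shares a locus with FADS2, was 1.30-fold higher. HPRT1, a purine salvage enzyme like PNP, was at 96.7 and 108 FPKM in the controls and 51.5 and 57.2 FPKM in the knockdown, and its 3′ UTR holds no GAGACCT. The interferon genes IFNB1, IFNL2 and IFNL3 were listed at 0 in all 4 libraries and IFNL1 at 0.178 FPKM in control replicate 1 and 0 in the others. PIGY (20.8 and 59.5 FPKM in control and knockdown replicate 1) and LUZP6 (137 and 10.6 FPKM) were listed at 0 in both replicate 2 libraries.

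Among 16083 words of 7 bases in the 3′ UTRs of 11661 genes, GAGACCT had the strongest link with lower values in the knockdown (z = -13.84 by rank, after a fit on 3′ UTR length, GC content and mean FPKM, against at most 5.1 in 100 permutations). It ranked first in run 1 (-12.09) and in run 2 (-13.07), stood in 1519 genes, and was in the 3′ UTR of 41.3% of 225 searched genes called lower and 8.3% of 180 called higher with the run as a term, against 13% of all searched genes. The word was picked in the same fold changes that gave these calls, so the shares describe the link and are no separate evidence for it. AURKA mRNA holds the word in the coding sequence of 8 of its 13 annotated transcripts, in the context AACACATACCAAGAGACCTACAAAA, and not in a 3′ UTR. The next lowest words, AGAGACC (-9.41) and AGACCTA (-6.96), are in the same stretch, but they overlap GAGACCT almost fully, so their place there adds little. Of all tested words, 16.3% occur in AURKA mRNA.

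Base composition or length of 3′ UTRs as the whole cause is argued against by words with the same bases in another order, of which 594 reached no lower than -5.0. Those z come after the fit on length and GC content, so they cover only what the fit left. Without the fit GAGACCT had a z of -13.53, and no other tested word lay below -9.24. GAGACCT was picked as the lowest word, so only the size of the gap counts here and not its rank. Differences of the kind seen between libraries of 1 group are argued against by the word's z of -0.62 between the controls and -0.05 between the knockdown libraries. These z cannot show a library difference that follows the group, which stays open. A candidate explanation is that a hairpin aimed at this stretch of AURKA also paired with 3′ UTRs through its first bases. Genes with GAGACCTA had a median 0.12 lower than genes with none of the forms (a difference of -0.12, 227 genes), those with GAGACCT and no following A had -0.079 (1292 genes) and those with AGACCTA alone -0.031 (639 genes), but the words were picked in the same fold changes, so this order is no test of the explanation. The prediction that more places lower a gene further was not met. The median of 194 genes with 2 or more lay 0.024 above that of 1325 genes with 1 (one-sided permutation p = 0.87). A median at or above that of genes with 1 was set beforehand as the outcome counting against the explanation. The 95% bootstrap interval of the difference, -0.03 to 0.064, also holds values below 0, so the explanation is not excluded. Loss of AURKA itself stays open and untested, since both knockdown libraries carry 1 hairpin label and no hairpin sequence was used here. DROSHA, KIF2C, AURKB, IL11, PNP and CCM2 hold the word, while STC1, AGR2, G0S2, ODC1, E2F1 and FOSL1 do not.

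With DROSHA lower, less repression of microRNA targets might be looked for. The mean z of 13 words matching abundant microRNAs (let-7 and miR-21 among them) was 0.01 with a standard error of 0.27, at percentile 38.9 of 10000 random sets of as many words and below the 0.63 that would have counted as relief. The highest of all words reached 4.05, within the permutations' range. The mean z of the microRNA words also lay below the 50th percentile of the random sets (0.094), the outcome set beforehand as counting against relief. That gap is smaller than the standard error. The expected size at a 1.66-fold lower DROSHA mRNA is not known either, which keeps the hypothesis open.

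The higher interferon list could come from several sources. A scaling factor of a library shifts list members and other genes in the same direction, low genes less on the log2(FPKM + 1) scale. Scaling between libraries as the whole cause is argued against by the list's median, which lay 0.286 above that of the 12110 other tested genes (0.012), with a 95% bootstrap interval of 0.176 to 0.652 over its 23 loci. The list's median lay 0.262 above that of the other genes in run 1 and 0.302 in run 2. The interval takes loci as independent. The list's own call is lost with an estimated correlation (adjusted p 0.689), a setting that also leaves few degrees of freedom. A response to the hairpin or its delivery cannot be told apart from loss of AURKA. The labels name 1 knockdown hairpin, and the controls are shC in the titles and mock-transfected in the design text, so it is not known whether they carried a hairpin.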
